A study of Gasterosteus aculeatus with 68 samples.

How the data were processed

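RNA from 7 tissues (eye, gill, heart, hypothalamus, liver, pectoral muscle and telencephalon) of threespine sticklebacks was measured on 68 custom Agilent arrays in 2 colours. Per the labels and the series' design text, each array carried 1 fish's RNA in the red channel (Cy5) and a common reference in the green channel (Cy3), and no dyes were swapped. The reference was pooled RNA of embryos 7 days after hatching, of a freshwater stock from an Alaskan lake (Bear Paw Lake). The fish came from a freshwater population (FTC, Washington) and a marine population (LITC, British Columbia). Per the design text, the 5 fish of each population were the offspring of a single wild-caught pair and all were reared in the same aquarium at 3.5 ppt, kept apart by a divider. Family and population therefore cannot be separated, and p-values measure the spread between siblings. Liver of freshwater animal 1 and pectoral muscle of marine animal 2 gave no array. Hypothalamus of freshwater animal 3 was left out because the design text excludes it for poor quality.

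The deposited scanner files hold spot intensities and log10 ratios written by Agilent Feature Extraction 9.5.3.1, per the file headers. The authors' value table holds a log2 ratio per spot, and the submitters' processing notes name limma with no version. Rows of that table follow the line order of the scanner files: over the 68 arrays its correlation with the scanner's log ratio was 0.954 to 0.979 by line and at most 0.013 in size by feature number. Column medians of the table lay between -0.0169 and 0.0278. Its slope against the scanner's log2 ratio was 0.679 to 0.811, and its exact background correction is not given in the sources used here.

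Mean intensities of each file were corrected for background with normexp (offset 50) and normalised within each array by loess, with control spots at weight 0, in limma 3.58.1 under R 4.3.3 with the data.table package, version 1.17.8. Spots flagged as outliers (0.16%) were left out. A few spots with a local background above 3 times the median of their array (0.0204% of spots, on 33 arrays) distorted the normexp fit of their whole array. Their background was set to the median of the array before the fit, and their values were left out. This repair was chosen after the data were seen, from the spread of each array against the value table and before any population was tested. The repaired values correlated at 0.9924 to 0.9996 with the authors' value table.

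Of 41661 spots per file, 1417 were controls and 40244 were probes of genes, with 39670 distinct sequences. Identical probes under 1 ID were averaged; those under different IDs were kept apart. The array names its probes by ID: 18569 features were 1 Ensembl gene each, 1321 named several Ensembl genes and 6 carried a symbol, while 65 incomplete IDs were left out. A probe entered a tissue when its red signal was well above background on at least a 0.5 share of the arrays of either population, and a gene took the median of its detected probes. The reference table given for this species holds no Ensembl IDs in its ensembl column (0 filled cells) and matched 0 of the array's IDs, so the genes are given by ID without symbol or position. Tests of gene lists and of clustering along chromosomes were planned and were not run for that reason.

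Freshwater and marine fish were compared within each tissue with limma (lmFit and eBayes with an intensity trend, Benjamini-Hochberg adjusted p under 0.05). Signed values are freshwater minus marine on the log2 scale. The population difference across tissues was tested on each fish's mean over the 4 tissues with all 10 fish (eye, gill, heart and telencephalon). Dependence of the difference on tissue was an F test over all 7 tissues with fish as a random block. Males and females were compared on the same means per fish with population as a covariate. Genes named for a comparison passed the threshold, had every detected probe in the direction of the gene and had no overlap between the arrays of the populations. The rule also asked for a symbol and for members of gene lists; without symbols both conditions were dropped, and at most the 2 IDs with the largest difference in each direction are given. For the sexes only the threshold was applied. Where a named gene was well above background on fewer than 0.5 of the arrays of a population, no fold is given, only the fitted log2 difference; this limit was set after the values were seen. Where it was on at least that share but not on all, the fold is as fitted and the number of such arrays is given. Dyes were not swapped, so a dye bias of a probe stays in its ratios to the reference; a bias equal on all arrays cancels in the difference between the populations.

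On simulated data, a 4-fold change was recovered for 95.5% of the changed genes in liver and 100% in gill. A 1.5-fold change was recovered for 35.8% in liver, 47.8% in pectoral muscle, 52.2% in gill and 82.1% in hypothalamus. Among 16987 simulated telencephalon genes, 11 unchanged ones were called. Only 66 or 67 genes were changed per fold, with independent noise for every gene and no slide or position effect. These values hold for that setting and do not estimate the false calls in the real data. The number of arrays limits the precision of each value. In eye 29.4 to 51.4% of probe spots and in hypothalamus 42.9 to 49.4% (32.4% on the excluded array) had a red signal well above background, against 55.9 to 91.2% in the other tissues; eye and hypothalamus were scanned together on a scanner and day of their own.

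The 68 arrays lay on 18 slides of 4 positions each. In eye, hypothalamus and telencephalon every slide held both populations, but freshwater arrays lay at positions 1 and 3 and marine arrays at positions 2 and 4. In heart, liver and pectoral muscle the positions were balanced, but most slides held a single population. Gill was partly unbalanced for both. Animal numbers name the same fish across the tissues of a population. They do not pair fish across populations, and no tissue had all same-numbered pairs correlating above 0.1.

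The alternatives, most of them chosen before the data were examined, covered the background correction, the normalisation, the filter on dim probes, the probe summary, sex, replicate and slide blocks, array weights, a fold minimum, a joint fit of all tissues, the authors' values and leaving out each fish. Added after seeing the data were the unrepaired debris spots, array position as a block, leaving out fish for sharing and tissue dependence, leaving out females for the sexes, and the features named by symbol.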

Results

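Expression was measured in 7 tissues of adult threespine sticklebacks (Gasterosteus aculeatus, aged 1.5 years) from a freshwater and a marine population, to ask which genes differ between the populations when the fish share an aquarium. Each population was represented by 1 male and 4 females. After exclusions, 5 freshwater and 5 marine arrays were compared in eye, gill, heart and telencephalon, 4 and 5 in hypothalamus and liver, and 5 and 4 in pectoral muscle. Values are log2 ratios of a fish to the embryonic reference pool.

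The populations did not overlap on any array for 9.89% of the genes in eye, 17.55% in gill, 16.06% in heart and 19.04% in telencephalon, where chance gives 0.79% for 5 against 5 arrays. The share was 20.35% in hypothalamus, 18.59% in liver and 14.66% in pectoral muscle, where chance gives 1.59% for 4 against 5. Between 8.65% of the tested genes in eye and 24.67% in telencephalon passed the limma test at an adjusted p under 0.05. Most of these differences were small: the median fold of the called genes lay between 1.34 in hypothalamus and 1.68 in liver and pectoral muscle. Gill had 651 called genes with at least a 2-fold difference, liver 636, heart 593, telencephalon 551, pectoral muscle 512, hypothalamus 256 and eye 163.

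**Figure D1:**
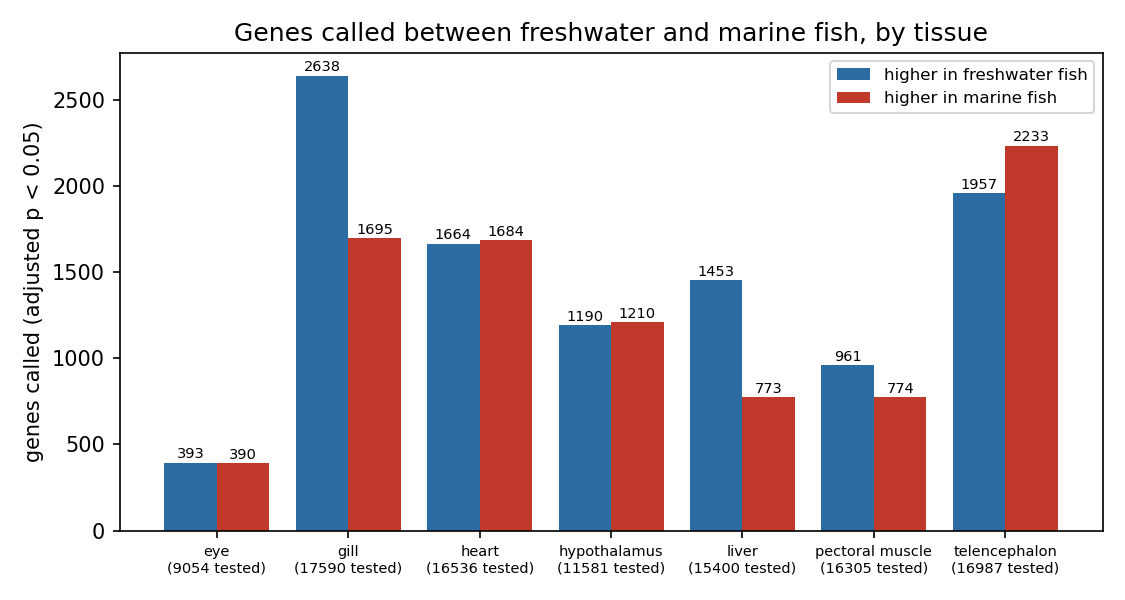
Number of genes (y axis) called at an adjusted p under 0.05 in each tissue (x axis, with the number of genes tested), as bars for genes higher in freshwater and genes higher in marine fish. Gill had 2638 genes higher in freshwater and 1695 higher in marine fish with loess; that balance turned to 29% higher in freshwater with median centring.

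Across tissues, with each fish's mean over eye, gill, heart and telencephalon, ENSGACG00000019826 was 20.6-fold higher in freshwater fish. Its log2 ratio was 1.15 ± 0.41 (SD, n = 5) in freshwater and -3.21 ± 1.29 (SD, n = 5) in marine fish (difference 4.36, SE 0.52, adjusted p = 9.41e-05), with 18 of the 20 marine arrays well above background. ENSGACG00000006908 was 8.74-fold higher in freshwater fish (3.13, SE 0.42, adjusted p = 0.000208), also with 18 of 20 marine arrays above background. Leaving out gill lowered its difference to 2.14. In the other direction, ENSGACG00000000644 was 21.7-fold higher in marine fish, at -3.54 ± 0.14 (SD, n = 5) against 0.90 ± 0.06 (SD, n = 5), with 14 of 20 freshwater arrays above background (adjusted p = 1.73e-11). ENSGACG00000003786 was also higher in marine fish (-3.46, SE 0.21, adjusted p = 4.59e-07), with 4 of the 20 freshwater arrays well above background. Of 8669 genes detected in the 4 tissues, 2905 were called, 1556 higher in freshwater and 1349 higher in marine fish, and 217 differed at least 2-fold. For 2221 of the called genes the difference had the same sign in all 4 tissues. Only 1326 were called with at least 2 detected probes all in the gene's direction in the 4 tissues. The share of calls higher in freshwater was 53.6% with loess and 30% with median centring, so the balance of directions depends on the normalisation. With slide as a block and fish as a random block 3080 genes were called; without eye 4982 were, over the larger set of genes detected in the other tissues.

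Both leading genes differed in the same direction in all 7 tissues. The rule that named them already required a single direction in eye, gill, heart and telencephalon. Only hypothalamus, liver and pectoral muscle could have gone the other way. ENSGACG00000019826 was higher in freshwater fish by 2.37 (SE 0.32) in liver to 5.24 (SE 0.75) in telencephalon, with adjusted p from 8.57e-05 in gill to 0.00554 in pectoral muscle. ENSGACG00000000644 was higher in marine fish in each tissue, from -2.24 (SE 0.23) in eye, where no freshwater array was well above background, to -6.12 (SE 0.14) in telencephalon. Counting over the separate fits, 2170 genes were called in the same direction in at least 3 tissues and 161 in all 7, of which 85 were higher in freshwater and 76 higher in marine fish. Called genes overlapped beyond independent lists in every pair of tissues; hypothalamus and telencephalon, for example, shared 730 genes higher in freshwater, where independent lists would share 159.88, and 780 higher in marine fish against 182.79. Their calls were opposite for 24 genes against 342.48. Across genes, the correlation of the differences was 0.706 between hypothalamus and telencephalon and 0.345 between gill and pectoral muscle; genes are not independent replicates, and all tissues share the same fish. Over pairs of tissues the mean correlation was 0.518, against a median of 0.282 and at most 0.5001 in other assignments of whole fish to 2 groups (100 assignments, the real one included). The mean covariance was 0.0977, against at most 0.0453.

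In gill, ENSGACG00000019485 was 351-fold higher in freshwater fish, at 5.27 ± 0.29 (SD, n = 5) against -3.18 ± 0.56 (SD, n = 5), with 3 of the 5 marine arrays well above background (adjusted p = 3.86e-09). The same gene differed by -0.03 (SE 0.16, adjusted p = 0.935) in heart. ENSGACG00000011548 was 63.3-fold higher in marine gill (-5.98, SE 0.25, adjusted p = 4.01e-08), and ENSGACG00000016064 was 52.4-fold higher there (-5.71, SE 0.34, adjusted p = 7.17e-07). ENSGACG00000006908 was higher by 6.08 (SE 0.62) in freshwater gill (adjusted p = 5.05e-05), a call that ended with array position as a block (4.44, adjusted p = 0.0818). Of 17590 tested genes 4333 were called, 60.9% of them higher in freshwater. That share was 47.8% with the scanner's own ratios and 29% with median centring, which moved the median difference of all genes by -0.194. With slide as a block 3804 genes were called, and of the 2427 genes called on the other slides, 97.7% had the same sign within the slide that held 2 arrays of each population. On the slide with 1 freshwater and 3 marine arrays that share was 96.2% of 1842. With array position as a block, 238 genes were called; only position 2 held both populations in gill.

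Kit ligand, the ligand of the KIT receptor that acts in pigment cells, is among the few features the array names by symbol, and was singled out after its values were seen. Its SALR probes read -1.17 (SE 0.16) lower in freshwater gill, a 2.25-fold difference (adjusted p = 0.000421), while the PaxB probes, of a slightly different sequence, differed by -0.37 (SE 0.20, adjusted p = 0.188). The PaxB probes passed in gill with median centring (-0.80, adjusted p = 0.0236), with females only (-0.58, adjusted p = 0.0466) and without freshwater animal 4 (-0.52, adjusted p = 0.0488). In liver the PaxB probes were 1.16 (SE 0.26) higher in freshwater fish (adjusted p = 0.0162) and the SALR probes differed by 0.54 (SE 0.29, adjusted p = 0.254). The liver call ended with slide as a random block (1.15, adjusted p = 0.2) and without freshwater animal 3 (1.09, adjusted p = 0.0538), and the gill call of the SALR probes ended with array position as a block (-1.21, adjusted p = 0.101).

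In liver, ENSGACG00000016064 went the opposite way to gill: it was 66.3-fold higher in freshwater fish, at 5.73 ± 0.35 (SD, n = 4) against -0.32 ± 0.48 (SD, n = 5), with 4 of 5 marine arrays well above background (adjusted p = 1.66e-06). ENSGACG00000006978 was 39.9-fold higher in freshwater liver (5.32, SE 0.82, adjusted p = 0.00323) with 4 of 5 marine arrays above background, a call that ended with slide as a random block (5.15, adjusted p = 0.0807). ENSGACG00000003537 was higher in marine liver (-5.72, SE 0.54, adjusted p = 0.000211; -6.43 without freshwater animal 2), with 1 of 4 freshwater arrays well above background, and ENSGACG00000000644 was 44.6-fold higher there, with 2 of 4 freshwater arrays above background (adjusted p = 6.04e-07). Of 15400 genes 2226 were called, 1453 higher in freshwater and 773 higher in marine fish. Every liver slide held a single population, and with slide as a random block 308 genes were called. Without freshwater animals 2, 3, 4 and 5 in turn the counts were 1431, 1251, 1420 and 1390; with median centring 1031 genes were called, and with females only 999.

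The telencephalon gave 4190 called genes of 16987, with 1957 higher in freshwater and 2233 higher in marine fish (46.7% higher in freshwater, and 71.2% with median centring). ENSGACG00000000869 was 103-fold higher in freshwater fish, at 5.48 ± 0.35 (SD, n = 5) against -1.22 ± 0.29 (SD, n = 5), with 4 of 5 marine arrays above background (adjusted p = 5.95e-10). ENSGACG00000019826 was 37.7-fold higher (5.24, adjusted p = 0.000428); marine animal 4 read 0.55 and the other marine fish -3.62 or less, and without that fish the difference was 6.09 (adjusted p = 3.71e-08). ENSGACG00000000644 was 69.3-fold higher in marine fish, with 4 of 5 freshwater arrays above background (adjusted p = 3.15e-10), and ENSGACG00000015680 was higher there too (-5.12, SE 0.11, adjusted p = 2.83e-10), with 2 of 5 freshwater arrays above background. With slide as a block 4122 genes were called. The genes called on the other slides had the same sign in 96.5% of cases within the first balanced slide, 97% within the second and 93.8% within the slide with 1 array of each population. Within a slide the populations lay at different positions here, as in eye, gill and hypothalamus. Such agreement within slides therefore bears on slides and cannot part population from position.

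In hypothalamus, ENSGACG00000019826 was 17.3-fold higher (adjusted p = 0.000356) and ENSGACG00000007546 7.01-fold higher in freshwater fish, the latter at 3.01 ± 0.05 (SD, n = 4) against 0.20 ± 0.02 (SD, n = 5), with 3 of 5 marine arrays above background (adjusted p = 3.44e-10). ENSGACG00000004657 (-2.97, SE 0.10, adjusted p = 2.96e-08) and ENSGACG00000002489 (-3.38, SE 0.71, adjusted p = 0.00697) were higher in marine fish; no freshwater array was well above background for either, and 4 of 5 marine arrays were for the latter. Of 11581 genes 2400 were called, 49.6% of them higher in freshwater, or 66.3% with median centring. The slide block left 2463 calls, and 91.9 to 98.2% of the genes called on the other slides kept their sign within a slide. The excluded array of freshwater animal 3, when added, lowered the count to 1427. With the debris spots left unrepaired 94 genes were called, and neither ENSGACG00000002489 (-2.67, adjusted p = 0.266) nor ENSGACG00000004657 (-2.31, adjusted p = 0.0649) passed.

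The prolactin releasing hormone gene prlh, also named on the array and singled out after its values were seen, gave a different answer by probe in hypothalamus. The probes named for the marine population LITC read -1.50 (SE 0.12) lower in freshwater fish (adjusted p = 1.47e-05), whereas those named BePa differed by -0.17 (SE 0.10, adjusted p = 0.257). With the debris spots left unrepaired the LITC probes gave -1.02 (adjusted p = 0.312), and with the scanner's own ratios -2.67. The probe pairs differ by 1 base (T33C or T32C, with the BePa base first and positions counted from 1 at the 5′ end of the probe as listed in the files). Read against each other in the same fish, the BePa probes exceeded the LITC probes by 0.55 ± 0.17 (SD, n = 4) in freshwater hypothalamus and fell short of them, at -0.78 ± 0.12 (SD, n = 5), in marine hypothalamus. The difference of 1.33 had an exact 2-sided permutation p of 0.00794, the smallest this design allows, with 9 such tests made and an adjusted p of 0.00794. Telencephalon showed a difference of 0.86 and the same exact p. For kit ligand, the BePa probe (the same sequence as the SALR probe) against the PaxB probe (A32T and T34C, counted likewise) gave -1.30 in gill and -0.61 to -1.83 over the 7 tissues, with every freshwater fish below every marine fish in each.

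**Figure D2:**
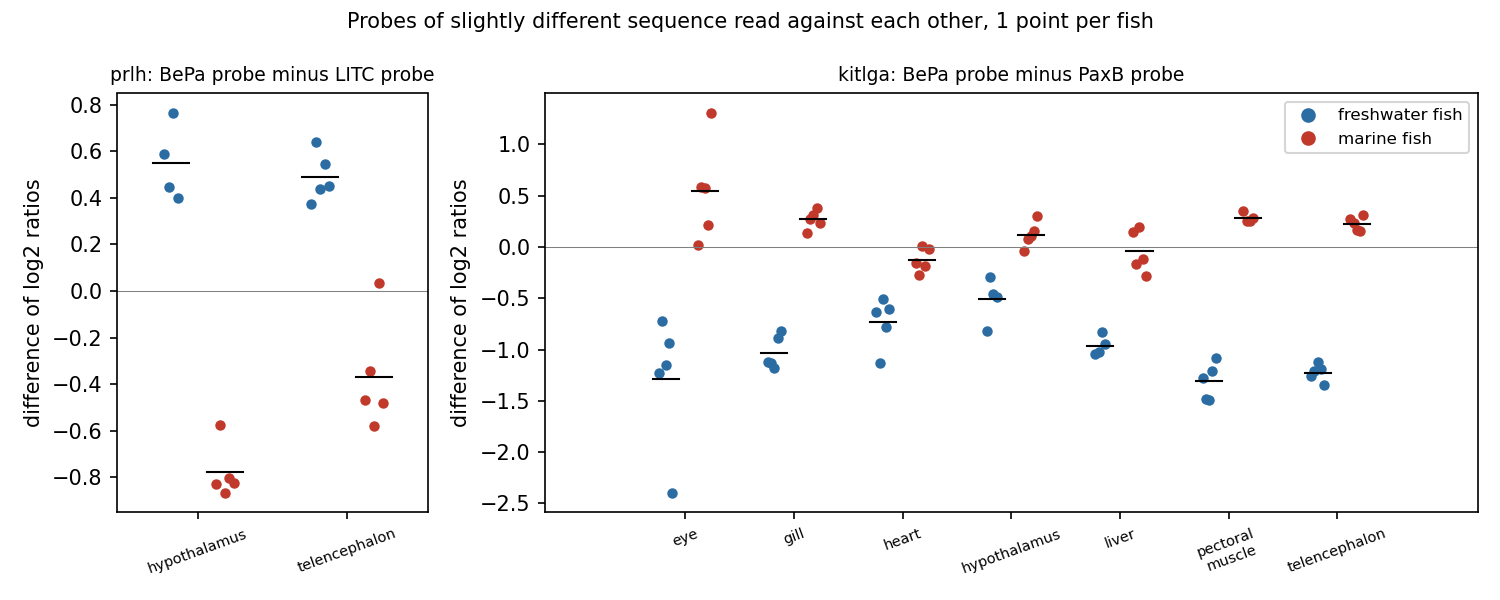
Log2 ratio of the BePa probe minus that of the probe for the other allele (y axis) in each tissue (x axis), 1 point per fish with the mean as a bar, for prlh on the left and kit ligand on the right. Freshwater and marine fish do not overlap in any tissue shown, with mean differences of 1.33 for prlh in hypothalamus and -1.30 for kit ligand in gill.

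In heart, ENSGACG00000012609 was 38.4-fold higher in freshwater fish, at 5.38 ± 0.08 (SD, n = 5) against 0.12 ± 0.67 (SD, n = 5) (adjusted p = 4.11e-07), and ENSGACG00000019826 was 28.1-fold higher (adjusted p = 0.000208). ENSGACG00000000644 was 43.7-fold higher in marine heart (-5.45, SE 0.10, adjusted p = 1.42e-10) and ENSGACG00000006308 20.4-fold higher (adjusted p = 0.000757). The call of ENSGACG00000006308 ended with slide as a block (-4.74, adjusted p = 0.105). Of 16536 genes 3348 were called, 1664 higher in freshwater and 1684 higher in marine fish. A full slide held each population in heart; slide as a block, which rests on the slide with 1 array of each, left 1126 calls. Within that slide 86.4% of the 3047 genes called on the other slides had the same sign. Array position as a block gave 2758 calls.

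In pectoral muscle, ENSGACG00000000869 was 38.5-fold higher in freshwater fish, at 6.35 ± 0.33 (SD, n = 5) against 1.08 ± 1.34 (SD, n = 4) (adjusted p = 0.000358), and ENSGACG00000004652 was 15.8-fold higher, with 2 of 4 marine arrays above background (adjusted p = 4.52e-05). ENSGACG00000002489 was 48.9-fold higher in marine muscle (-5.61, SE 0.19, adjusted p = 8.79e-07) and ENSGACG00000007458 22.5-fold higher (adjusted p = 1.27e-05). Marine animal 2, which was near freshwater level for ENSGACG00000002489 in its 6 other tissues, gave no muscle array; in those tissues the difference was -2.82 (SE 0.49) in eye to -4.57 (SE 1.09) in liver. Of 16305 genes 1735 were called, 961 higher in freshwater and 774 higher in marine fish. Every pectoral muscle slide held a single population. Slide as a random block gave 6042 calls with an estimated slide correlation of -0.181, and array position as a block gave 1111. With a single population per slide, a negative correlation shrinks the error of the population difference, so the 6042 calls are not a correction for slide. Without freshwater animal 2 the count was 1033, without freshwater animal 3 1006 and without marine animal 4 1149; with median centring it was 887.

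In eye, ENSGACG00000000869 was higher in freshwater fish (4.07, SE 0.44, adjusted p = 0.000238), with no marine array well above background. ENSGACG00000019826 was 8.64-fold higher, with 3 of 5 marine arrays above background (adjusted p = 0.000376). The call of ENSGACG00000000869 ended with the debris spots left unrepaired (3.41, adjusted p = 0.0723), and with the scanner's own ratios its difference was 8.46. ENSGACG00000002788 was higher in marine eye (-4.23, SE 0.17, adjusted p = 4.2e-07), with no freshwater array above background; its size was unsettled, from -1.89 without freshwater animal 3 to -8.34 with the scanner's own ratios. ENSGACG00000013895 was 7.33-fold higher, at -0.94 ± 0.31 (SD, n = 5) against 1.94 ± 0.28 (SD, n = 5) (adjusted p = 5.04e-06). Of 9054 genes 783 were called, 393 higher in freshwater and 390 higher in marine fish (50.2%, against 38.5% with median centring). Slides mattered here: 2882 genes differed between the 3 eye slides, and with slide as a block 1570 genes were called between the populations. Of the genes called on the other slides, 95 to 99% had the same sign within a slide. The count was 488 without freshwater animal 3, 518 without marine animal 4 and 155 with the debris spots left unrepaired.

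The size of the population difference depended on tissue for 8426 of 18866 genes (44.7%, limma F test with fish as a random block). Slide and position were not in this test. Population goes with slide in some tissues and with position in others, so technical offsets can add to the count and were not separated from it. A gene entered this test if it was detected in any of the 7 tissues. The count can therefore include genes that were too dim to read in some tissues, and these were not counted apart. Over these genes the 7 differences spanned a median range of 0.77. The largest difference of a called gene lay most often in liver (2204 genes), gill (1991) and pectoral muscle (1510), and least often in eye (174). These counts compare raw differences, and the tissues differ in spread (median residual SD 0.235 in liver, 0.204 in pectoral muscle, 0.176 in gill, 0.183 in eye and 0.126 in hypothalamus) and in the number of genes detected, lowest in eye. In liver and pectoral muscle population also goes with slide, so the counts do not rank the tissues by biological difference. For ENSGACG00000016064, not tested in eye on its own, the tissue test gave an adjusted p of 1.02e-34. In all, 396 called genes had opposite signs in 2 tissues at p under 0.001 in each. ENSGACG00000000869, much higher in freshwater telencephalon, was lower in freshwater gill (-1.30, SE 0.40, adjusted p = 0.0335).

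**Figure D3:**
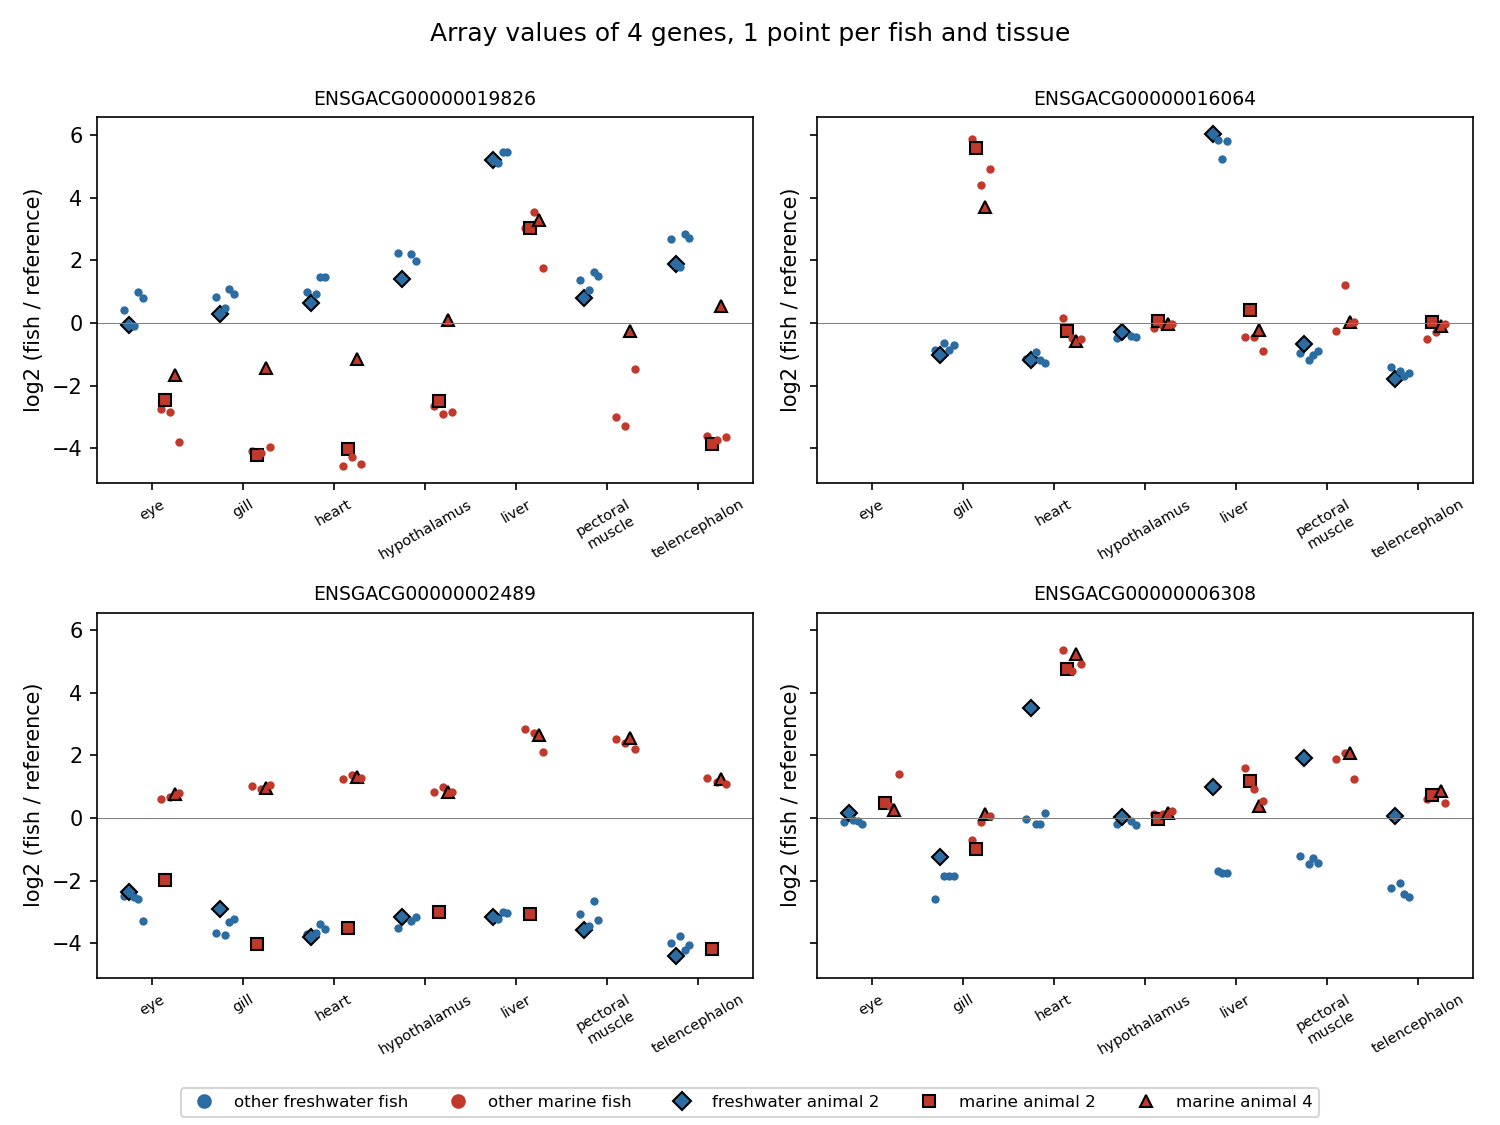
Log2 ratio to the reference (y axis) of 4 genes in each tissue (x axis), 1 point per fish, with freshwater and marine fish in 2 colours and 3 fish marked by shape. ENSGACG00000016064 was 52.4-fold higher in marine gill and 66.3-fold higher in freshwater liver, and marine animal 2 lay near the freshwater fish for ENSGACG00000002489; ENSGACG00000016064 has no points in eye, where it was too dim to test.

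Males and females were compared on 2 males and 8 females. ENSGACG00000010827 was 1.99-fold higher in females (-0.99, SE 0.08, adjusted p = 0.000528) and ENSGACG00000004613 1.92-fold higher (adjusted p = 0.00442). ENSGACG00000012640 was 1.78-fold higher in males (0.83, SE 0.09, adjusted p = 0.00218) and ENSGACG00000006281 1.69-fold higher (adjusted p = 0.00883). Of 8669 genes 165 were called, 159 higher in females and 6 higher in males. The median fold of the genes higher in females was 1.50, with quartiles of -0.69 and -0.45 on the log2 scale. Without the marine male, with 1 male left whose spread is taken from the other fish, 2 genes were called. ENSGACG00000012640 then missed the threshold at nearly the same difference (0.82, adjusted p = 0.111), and ENSGACG00000006281 (0.47, adjusted p = 0.317) and ENSGACG00000004613 (-0.59, adjusted p = 0.111) at smaller ones. The kitlgaY probes are named for a Y-linked copy of kit ligand. In liver they were well above background on both male arrays and on none of the 7 female arrays, and likewise in pectoral muscle. In gill 1 of 2 male and 3 of 8 female arrays were, in heart 2 of 2 and 3 of 8, and in telencephalon 0 of 2 and 2 of 8. In eye and hypothalamus no compared array of either sex was.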

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

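The tests of array position, of prlh probes and of the marine male were chosen after the results were seen; those of slides, of probe mismatch over all genes and of other splits were set beforehand, but for slides and positions a margin of 2 standard errors above the highest reassignment was added after the values were seen.

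A chance division of these fish can be excluded as the source of the differences between the groups. The splits cannot tell population from family, because the fish of each population were the offspring of a single wild-caught pair. In each of the 7 tissues, across tissues, for sharing and for tissue dependence, 1 of 100 splits of the samples (the real one) gave a count as large. The real counts and the highest of the other splits were 783 and 0 in eye, 4333 and 2 in gill, 3348 and 1 in heart, 2400 and 691 in hypothalamus, 2226 and 364 in liver, 1735 and 11 in pectoral muscle, and 4190 and 2 in telencephalon. They were 2905 and 1 across tissues, 2170 and 0 for genes called in at least 3 tissues, and 8426 and 2312 for tissue dependence.

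The tissue dependence itself was singled out because the population difference differed between tissues for 8426 genes. Slide and position were not in that test and go with population in a way that differs between tissues, so both stay open as a source. ENSGACG00000016064 (adjusted p = 1.02e-34) and ENSGACG00000000904 (adjusted p = 2.37e-09) had the largest called differences of opposite sign among features of 1 Ensembl gene, ranked by the smaller of the 2 opposite differences. ENSGACG00000000904 was 7.08-fold higher in freshwater telencephalon (limma, adjusted p = 4.62e-06). It was 3.65-fold higher in marine pectoral muscle (limma, adjusted p = 0.0351), where every slide held a single population.

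Slides and positions are the first technical explanation for the calls, and no tissue is free of both. If slides had made the heart calls, called heart genes would share their sign with the slide-balanced telencephalon no more than after reassigning fish; 84.3% did, against at most 81.9% (standard error 0.64 over 3208 genes), which argues against slides as the whole source. The test left slides open in liver (75.5% against 76.6%) and in pectoral muscle, where the share was above the highest reassignment by less than its standard error of 0.89 (84.2% against 83.8%), so slide and population cannot be told apart there. For position, 82.9% of telencephalon calls shared their sign with the position-balanced heart, against at most 79.9%, and 0 genes were called between positions in heart, liver or pectoral muscle by limma (752, 560 and 705 at an unadjusted p under 0.05). Position stayed open for eye, above the highest by less than its standard error of 1.09 (89.7% against 88.7%), and for hypothalamus (81% against 82.9%). These standard errors treat genes as independent and do not measure the spread between fish. The margin that parts heart and telencephalon from pectoral muscle and eye is therefore only nominal. Gill, partly unbalanced for slide and position, was given neither test. Array position as a block gave 238 gill calls against 4333 without it. Most positions held a single population there, so position stays open for gill.

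Probe mismatch is the second explanation, since a base difference under a probe lowers its signal without any change in RNA. Over 1689 genes with probes that do not overlap, both detected in the 4 tissues, 87% of the 576 called on the first probe had the same sign on the second. Mismatch alone would give about 50%, so this argues against it as the only source of the calls in this set. However, 75.2% of genes not called on the first probe also had the same sign, and 59.5% of the 576 were called on the second probe too with that sign. The share of calls that mismatch made is therefore not settled. Of 55 genes called at 2-fold or more on the first probe, 40% reached 2-fold on the second, and 14407 of 19976 genes have overlapping probes, which could both cover 1 mismatch. For prlh in hypothalamus the probe ratio moved by 1.328 between populations, so mismatch may account for the LITC probe's call. The ratio does not say which probe was affected, so the small difference on the BePa probe is no firmer. The kit ligand probe ratio moved by -0.61 in heart to -1.83 in eye, so mismatch is open for its gill and liver calls too. The 2 genes read on all 20 arrays of a population and none of the other, against at most 0 in other splits (1 of 100 splits as large), had a second probe in the same direction for 50%; neither second probe was silent in the other population and 1 read on all 20 of its arrays, which goes with mismatch in too few genes to decide, and a biological difference between the populations or families stays open, untested beside these.

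Single fish stood far from their siblings in 11 of 64 sets of values of named genes, where chance sets apart about 1 in 20 independent sets. These sets repeat genes and fish over tissues, so the count cannot be weighed against that rate. ENSGACG00000019826 was high in marine animal 4 in heart (-1.14, next -4.04), hypothalamus (0.08, next -2.49), telencephalon (0.55, next -3.62) and on average across tissues (-0.92, next -3.65). Marine animal 2 was low for ENSGACG00000002489 in hypothalamus (-3.02, next 0.83). Freshwater animal 2 was high for ENSGACG00000006308 in heart (3.52, next 0.17), for ENSGACG00000003537 in liver (2.82, next 0.11) and for ENSGACG00000006908 in gill (7.06, next 6.25). The others were ENSGACG00000012609 in heart of marine animal 3 (-1.05, next 0.21), ENSGACG00000002788 in eye of freshwater animal 5 (-2.76, next -2.16) and ENSGACG00000007546 in hypothalamus of marine animal 1 (0.16, next 0.21). Every one of these calls remained without the fish concerned, some at another size: ENSGACG00000019826 went from 4.81 to 5.45 in heart, from 4.11 to 4.67 in hypothalamus, from 5.24 to 6.09 in telencephalon and from 4.36 to 4.94 across tissues, ENSGACG00000002489 from -3.38 to -4.15, ENSGACG00000006308 from -4.35 to -5.06 and ENSGACG00000003537 from -5.72 to -6.43. Among array measures, freshwater eye of animal 5 had 51.2% of probes with red signal above background, next 37.7%; marine eye of animal 5, the other array of that slide, had 51.4%, and the remaining eye arrays 39.2% or less.

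The sex calls rest on the marine male, and an unusual marine male is a candidate explanation. Of the 155 genes called with that fish as the only male and also tested on both, 90.3% had the same sign in the freshwater male against the females of its own population, compared with 54.6% of all tested genes; the spread came from the other fish, since 1 male has none. Of the 24 other pairs of a marine and a freshwater fish put in the place of the males, 3 gave at least 20 genes to compare, and freshwater and marine animal 5, both female, gave 141 genes and 87.2%. That pair shared a slide in eye, heart and telencephalon, and the males shared one in eye and telencephalon. Sex and an unusual male or pair of fish therefore cannot be told apart here, with 2 males and too few pairs to compare.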

How the results depend on the processing

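Unrepaired debris spots, array position, leaving out fish for sharing and tissue dependence, leaving out females for the sexes and the features named by symbol were chosen after seeing the data. Of the alternative values of named genes, 1043 kept direction and side of the threshold, 13 lost the call, 3 gained it and 1 reversed: prlh by its BePa probes in hypothalamus was 0.003 with debris not repaired, against -0.17. The sizes moved more: the scanner's log ratios without loess gave the largest difference for 29 of 41 named values and one larger by at least 1 log2 unit for 21, such as -6.93 against -3.38 for ENSGACG00000002489 in hypothalamus. Those ratios also lack the normexp correction and its offset, so the larger sizes cannot be put down to loess. Any other alternative moved only 4 values that far: ENSGACG00000002788 in eye (-1.89 without freshwater animal 3), ENSGACG00000006908 in gill (4.44 with array position as a block), ENSGACG00000019826 in heart (6 with slide as a block) and ENSGACG00000004652 in pectoral muscle (2.35 with no filter on dim probes). Gene lists and clustering along chromosomes were not run, because the IDs had no symbols or positions. Where no other cause is named, the cause was not tested.

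With a minimum of 2-fold the counts were 163 in eye, 651 in gill, 593 in heart, 256 in hypothalamus, 636 in liver, 512 in pectoral muscle, 551 in telencephalon and 217 across tissues, fewer by construction. Median centring gave 6810 in gill, 1031 in liver and 887 in pectoral muscle. The scanner's log ratios without loess gave 1770 in eye. No filter on dim probes gave 509 in eye and 4825 across tissues, over more genes. At least 2 detected probes in the gene's direction gave 1326 across tissues, and leaving out eye 4982. Debris not repaired gave 155 in eye and 94 in hypothalamus. Females only gave 409 in eye and 999 in liver, with fewer fish. Numbers did not pair fish, and the replicate block gave 1428 in eye, 1299 in liver and 530 in pectoral muscle and stayed within 1.5 times elsewhere; every fish correlated best with its own number in no tissue. Slide as a block gave 1570 in eye and 1126 in heart, and as a random block 308 in liver (slide correlation 0.307) and 6042 in pectoral muscle (-0.181). The pectoral muscle count rests on that negative correlation and is not a correction for slide. Array position as a block gave 238 in gill, 1471 in liver and 1111 in pectoral muscle. Array weights gave 1336 in eye and 3410 in liver. All tissues in 1 fit gave 1282 in hypothalamus, 5337 in liver and 4308 in pectoral muscle, where tissues share 1 estimate of the spread. Including freshwater animal 3 gave 1427 in hypothalamus. Sharing was 4037 genes for at least 2 tissues and 1224 for at least 4.

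Without 1 fish the counts were 488 to 844 in eye, 3348 to 4127 in gill, 2599 to 3427 in heart, 1797 to 2411 in hypothalamus, 1251 to 2686 in liver, 1006 to 1647 in pectoral muscle, 3533 to 3882 in telencephalon, 2559 to 2896 across tissues, 6260 to 8367 for tissue dependence, 1619 to 2078 for sharing and 2 to 189 for the sexes. Pectoral muscle fell to 1033 without freshwater animal 2, 1006 without freshwater animal 3 and 1149 without marine animal 4, and liver to 1431, 1251, 1420 and 1390 without freshwater animals 2, 3, 4 and 5. Low red signal over background limits eye and hypothalamus, where fewer genes could be tested.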

Other observations

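The test of fish was chosen after single fish had been seen to stand apart, and what its shuffles should show was written before they were run; all other values in this part were also chosen after seeing the data. For some genes, single fish stood apart from the rest of their population in tissue after tissue; the genes given here also differed between the populations. ENSGACG00000002489 was near freshwater level in marine animal 2 in every tissue of that fish: -1.97 in eye, -4.03 in gill, -3.5 in heart, -3.02 in hypothalamus, -3.06 in liver and -4.18 in telencephalon, where the 4 other marine fish read between 0.61 and 2.85 in those tissues. For ENSGACG00000019826, marine animal 4 was above the other marine fish in eye, gill, heart, hypothalamus, pectoral muscle and telencephalon, and in liver it was not (3.3, with marine animal 3 at 3.54). Freshwater animal 2 read 3.52 in heart, 0.99 in liver, 1.92 in pectoral muscle and 0.06 in telencephalon for ENSGACG00000006308, where the other freshwater fish lay at 0.17 or below. In eye (0.17, next -0.07), gill (-1.25, next -1.86) and hypothalamus (0.02, next -0.09) it stood apart by less.

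Over the 4 tissues with all fish, 1586 of 8585 genes (18.5%) differed between fish of the same population, by a limma F test. Shuffling fish within each tissue and population gave at most 79 genes, and 1 of 100 orders (the real one) gave as many, so chance can be excluded. Females alone gave 1117 genes, 1055 of them also called with males. Array position partly follows the fish, since freshwater animal 1 lay at position 1 in each of these tissues; with position in the model 1974 genes were called, 1407 of them also called without it. Slides follow the fish in part too; with slide in the model 1266 genes were called, 1031 of them also called without it, and the shuffles then gave at most 17. On simulated data a shift of 1 fish by 2-fold was recovered for 86% of genes, with 12 false calls. Fish effects were called for 17.8% of the 2873 genes called between the populations and for 18.8% of the others, a difference that was not tested. The calls were spread unevenly over the fish. Marine animal 5 lay farthest from its population in 393 of the 1586 genes, and marine animal 3, the marine male, in 281. Freshwater animal 4, the freshwater male, lay farthest in 45 and the other fish in 69 to 156. The same count over all tested genes is not given, so the unevenness is not shown to be particular to the called genes. The eye array of marine animal 5 also stood out, with 51.4% of probes above background, but freshwater animal 5, at 51.2% on the same slide, lay farthest in only 105 genes; whether its arrays or the fish itself account for the share of marine animal 5 was not tested. In 65 called genes a fish lay at least 2-fold from its population. The arrays hold no genotypes of the fish.

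Genes at least 2 log2 units higher in a tissue than in every other tissue were also compared. Fisher's exact test, used here, counts genes as independent. They come from the same fish, so its p-values do not measure the spread between fish. In gill 167 of 378 such genes were called between populations, 44.2% against 24.2% of other genes (Fisher's exact test, adjusted p = 4.14e-16 over 7 tissues); their balance, 98 higher in freshwater and 69 higher in marine fish, turned to 28 and 159 with median centring. In pectoral muscle 44 of 206 were called (21.4% against 10.5%, adjusted p = 2.12e-05), 40 higher in freshwater and 4 higher in marine fish, with 29 and 4 under median centring and 42 and 3 with the scanner's ratios; slide and population are confounded there. In eye 5 of 163 were called, fewer than among other genes (3.1% against 8.8%, adjusted p = 0.0164), and their median spread between fish was 0.562 against 0.181. The other tissues did not pass: heart had 30.3% against 20.2% (adjusted p = 0.0812), hypothalamus 41.7% of 12 genes against 20.7% (adjusted p = 0.115), liver 16% against 14.4% (adjusted p = 0.313) and telencephalon, in the other direction, 20.8% against 24.7% (adjusted p = 0.218).

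The excluded hypothalamus array of freshwater animal 3 had 32.4% of probes with red signal above background and correlated at 0.891 with its group, where the other freshwater arrays had at least 46.8% and 0.943.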
